A study of Mus musculus with 6 samples.

How the data were processed

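RNA was measured by poly(A) sequencing in 6 libraries of HT22 cells, an immortalised line derived from mouse hippocampal neurons. Per the labels, 3 libraries came from cells exposed to interleukin 17 (IL-17) and 3 from untreated control cells; dose and duration were not given in the sources used here. Groups were taken from the treatment label of each sample. Per the labels' protocols, RNA was extracted with TRIzol and its integrity checked on a Bioanalyzer. Polyadenylated RNA was captured on oligo(dT) beads and fragmented, second strands were marked with dUTP, and paired-end sequencing was run on a NovaSeq instrument, per the labels' protocols. A SMARTER mRNA kit is also named there, and how the 2 descriptions fit together is not stated.

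The authors deposited a single table of FPKM values (fragments scaled by transcript length in kilobases and by the number of mapped fragments), with 26595 Ensembl genes and 1 column per library. Fastp, StringTie, edgeR and genome build mm10 are named, without versions or order, per the submitters' processing notes. The aligner and annotation release were not given in the sources used here. FPKM is a share of each library, so a few very abundant transcripts can lower the values of all others. Whether strand was used in quantification was not stated, so values of overlapping, antisense and near-identical genes are uncertain. Symbols and coordinates came from GENCODE vM21 on GRCm38, the assembly also called mm10; 26525 identifiers matched and 70 did not.

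The table holds no counts, so sequencing depth is not known directly. For 10445 genes with 1 annotated transcript, FPKM times transcript length in kilobases was searched within a narrow window for its fullest bin, 5e-04 wide. That bin held 132 to 168 genes per library. If it marks 1 fragment, the libraries held 15600000 to 17500000 mapped fragments. The window limited the depths that could come out, so similar depth is not shown by this estimate. The number of genes above 0 ran from 20959 to 21633.

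The FPKM values were used as deposited, with no further scaling, and analysed as log2(FPKM + 1), a scale that understates the change of genes with low values. Genes with a mean FPKM of at least 0.5 over all 6 libraries were tested, which kept 12953 and left out 13642. Each gene was tested with limma 3.58.1 in R 4.3.3, with a mean-variance trend and group as the sole term, and Benjamini-Hochberg adjustment; genes with an adjusted p under 0.05 were called. Intervals are at the 95% level. Jak1, Stat6, Il17ra, Il17rc and Traf3ip2 were also given an exact two-sided permutation test of their FPKM, for which 3 against 3 libraries cannot go below p = 0.1. In simulated data for this comparison, with 200 of 12953 genes changed, limma recovered 14% of genes changed by 0.3 on the log2 scale, 76% at 0.5, 98% at 1 and 100% at 2. Of 154 calls in that simulation, 10 were unchanged genes, and 0 calls arose when no gene was changed. The simulated errors were normal and independent between genes, with variances drawn from limma's own fitted model. These rates therefore describe data that meet the model, and may not hold for libraries with shared differences between genes.

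Before the data were examined, 27 gene lists were fixed, together with the tests, the rule for naming genes and the other settings to be tried. The 25 lists with at least 5 tested genes were compared with the other genes by camera in limma, with a preset correlation of 0.01 between genes. Camera with an estimated correlation and the fry test were run beside it. Each list also has the number of members called over all tested genes and the number when p-values were adjusted over the list alone. The hypoxia and glycolysis list counts 30 tested entries for 29 symbols, because 1 symbol has 2 identifiers.

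Named genes are Jak1, Stat6, Il17ra, Il17rc and Traf3ip2; the 10 higher and 10 lower called genes with the largest changes; up to 4 called members of each list with the smallest p, or up to 2 uncalled members where none was called; and the 5 genes of highest mean level. The genes with the largest changes needed non-overlapping groups and a mean FPKM of at least 2 in the higher group. Predicted or clone-named genes, duplicated symbols and pseudogenes were left out of those. A gene that this rule takes in is not reported here. Other genes are named only where the text says they were chosen after their values were seen.

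The alternatives changed the pseudocount, the filter, the scaling (TMM factors computed on the FPKM, quantile normalization or TPM), the variance model and the thresholds, added the replicate number as a block, or left out 1 library at a time. Added after the data were seen were a correction for GC content and transcript length, protein-coding genes alone, the removal of lung and liver transcripts, the removal of IL-17 library 1 with control library 3, and a robust variance prior. No library, and 0 columns of values, were left out of the main comparison.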

Results

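Gene expression was measured in 3 HT22 libraries from cells exposed to IL-17 and 3 from untreated cells. Per the labels these are HT22 cells, a line derived from mouse hippocampal neurons. IL-17 is a cytokine made mainly by T cells that acts through a receptor of Il17ra and Il17rc chains. The stated purpose was to relate IL-17 to JAK1-STAT6 signalling. Values are FPKM, summing to between 365534 and 383093 per library. Correlations of log2 values across genes ran from 0.986 to 0.992 between libraries, and genes are not independent replicates. IL-17 library 1 correlated more with control library 2 (0.9924) than with IL-17 libraries 2 (0.9915) and 3 (0.9880). Its median absolute log2 difference was smaller from IL-17 library 2 (0.0896) than from control library 2 (0.101). The leading principal component held 33.7% of the variance, with IL-17 libraries at -0.78, -13.3 and -17.1 and control libraries at 10.3, 12.2 and 8.72. The samples are not said to come from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

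Among the genes with the largest increases after IL-17 were those of several secreted proteins. Il6, a cytokine, rose from 3.50 ± 0.197 to 17.8 ± 0.918 FPKM (SD, n = 3 per group), a log2 fold change of 2.06 (SE 0.06) on the log2(FPKM + 1) scale. Csf3, the granulocyte growth factor, rose from 3.46 ± 0.111 to 15.1 ± 1.35 FPKM (log2 fold change 1.85, SE 0.07). Lcn2, an iron-binding acute-phase protein, rose from 18.8 ± 0.481 to 59.1 ± 2.80 FPKM, and Chil1, a secreted chitinase-like protein, from 16.6 ± 1.14 to 65.6 ± 2.57 FPKM. Nos2, the inducible nitric oxide synthase, rose from 59.2 ± 3.38 to 181.7 ± 14.03 FPKM, and the kinase gene Pim2 from 11.8 ± 0.903 to 45.9 ± 3.03 FPKM. Aldh3a1, an aldehyde dehydrogenase, rose by 1.39 (SE 0.07) on the log2 scale. For these genes the adjusted p-values by limma with Benjamini-Hochberg adjustment lay between 2.2e-05 for Il6 and 0.000125 for Aldh3a1, and their values did not overlap between the groups.

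Il19, Lyz1 and Serpina3n, at lower levels, completed the 10 largest increases, with log2 fold changes of 1.40 (SE 0.19), 1.39 (SE 0.25) and 1.37 (SE 0.21). Lyz1 was at 1.12 FPKM in control library 3 against 0.138 and 0.127 in the other controls, a spread it shared with lung transcripts. These 3 calls were lost when certain single libraries were left out. By limma with Benjamini-Hochberg adjustment, the adjusted p of Il19 became 0.0531 without IL-17 library 2, 0.071 without control library 1 and 0.0614 without control library 2. That of Serpina3n became 0.0928, 0.0917 and 0.0573 without control libraries 1, 2 and 3. That of Lyz1 became 0.0629, 0.111 and 0.128 without IL-17 libraries 1, 2 and 3, and 0.133 and 0.14 without control libraries 1 and 2. The Lyz1 call was also lost with a pseudocount of 0.1 (0.078) or 0.5 (0.054), no filter (0.168), quantile normalization (0.0501), TPM scaling (0.0508) and a robust prior (0.071), and its log2 fold change ran from 1.10 to 2.76 over the alternatives.

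Most of the interferon-stimulated genes fixed beforehand fell, and some were among the largest decreases. Cxcl10, a chemokine, fell from 158.7 ± 7.12 to 62.0 ± 0.821 FPKM, a log2 fold change of -1.34 (SE 0.05; adjusted p = 4.0e-05 by limma with Benjamini-Hochberg adjustment). Vcam1, an adhesion molecule, fell from 13.9 ± 0.472 to 6.53 ± 0.668 FPKM. Isg15, a ubiquitin-like protein, fell from 1246 ± 123 to 727.7 ± 30.8 FPKM, and Irf7, a transcription factor of the interferon response, from 135.5 ± 1.42 to 80.8 ± 0.879 FPKM. Cmpk2, Igtp, Oasl1, Ifit3b and Oasl2 fell by 0.89, 0.81, 0.81, 0.79 and 0.75 on the log2 scale. Of these genes, Isg15, Irf7 and Oasl2 belong to the list and the others do not. Of the 31 interferon-stimulated genes fixed beforehand, 24 fell, 0 rose and 7 did not pass, and 30 fell when adjusted over the list alone. All 31 had negative log2 fold changes, with a median of -0.51. The list was lower than other genes by camera (adjusted p = 4.39e-40), and adjusted p = 0.0038 with an estimated correlation. Without both IL-17 library 1 and control library 3, in which lung or liver transcripts differed from the rest of their group, 14 of the 31 fell, with fewer samples and a median of -0.50. In that fit some lung and liver transcripts still differed between the groups. Sftpc, a surfactant gene chosen after its values were seen, was at 25.8 and 35.3 FPKM with IL-17 and 0.331 and 0.170 in controls. Alb, the albumin gene chosen likewise, was at 6.75 and 10.8 FPKM with IL-17 and 47.1 and 40.4 in controls. Here and below, that fit therefore cannot separate an effect of IL-17 from lung or liver material.

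**Figure D1:**
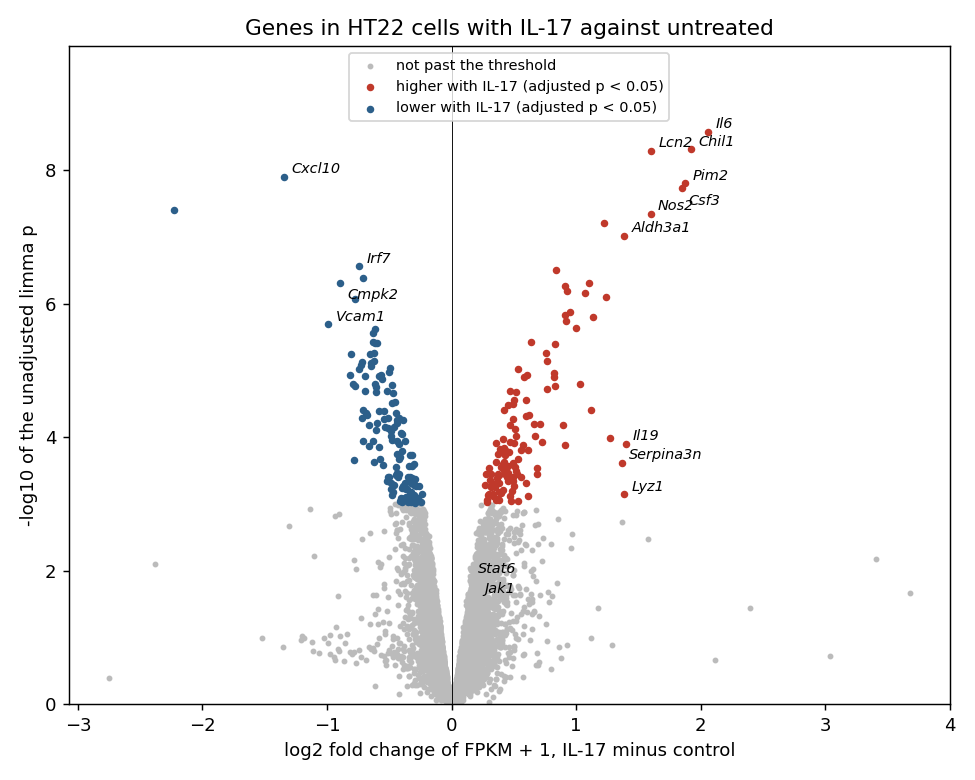
Each point is a tested gene in HT22 cells, with its log2 fold change of FPKM + 1 (IL-17 minus control, 3 libraries each) on the horizontal axis and the negative log10 of its unadjusted limma p on the vertical axis. Red points are the 123 genes called higher and blue points the 129 called lower; Il6, Chil1 and Lcn2 lie farthest up on the right, Cxcl10 on the left with Gm20521 unlabelled beyond it, and Jak1 and Stat6 are grey.

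In total, 252 of the 12953 tested genes changed, 123 higher and 129 lower, by limma at an adjusted p under 0.05. Of these, 20 changed by at least 1 on the log2 scale, 18 higher and 2 lower, and the median absolute change of the called genes was 0.49. The 2 lower genes were Cxcl10 and, named after its values were seen, Gm20521, a gene model overlapping Bcl2l2 and Pabpn1 on the same strand. It was listed at 0 in all IL-17 libraries and at 4.32, 3.15 and 3.67 FPKM in controls, and its value depends on how shared reads were assigned. Groups did not overlap for all 252 called genes and for 24.2% of tested genes, where chance gives 10%. The count was 117 without IL-17 library 2, 150 without IL-17 library 3, and 161, 129 and 147 without control libraries 1, 2 and 3. Under TMM scaling the split was 110 higher and 203 lower.

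Neither gene of the JAK1-STAT6 pair passed the test over all genes. Jak1 is a cytokine receptor kinase gene on chromosome 4, from 101152367 to 101265282 (GRCm38, minus strand). It stood at 10.2 ± 0.571 FPKM with IL-17 and 8.74 ± 0.75 in controls (n = 3 each), a log2 fold change of 0.21 (SE 0.07, 95% interval 0.04 to 0.38). Stat6, the transcription factor gene of IL-4 and IL-13 signalling, lies on chromosome 10 from 127642986 to 127660957 (plus strand). It stood at 28.5 ± 0.573 and 25.5 ± 0.457 FPKM, a log2 fold change of 0.15 (SE 0.05, 95% interval 0.04 to 0.26). Neither was called by limma with Benjamini-Hochberg adjustment over all genes (adjusted p = 0.221 for Jak1 and 0.163 for Stat6). Both belong to 2 of the fixed lists. Adjusted over the list alone, neither passed among the JAK-STAT components (0.0867 and 0.0504), while among the JAK1-using receptors and STAT6-axis genes Stat6 passed (0.0363) and Jak1 did not (0.0607). For both, every IL-17 value lay above every control value, and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. Stat6 passed in 1 of 21 alternatives, with array weights (limma adjusted p = 0.0396, where the range over the alternatives was 0.0396 to 0.437). The FPKM measure transcript levels, not phosphorylation.

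Other signalling genes around this pair moved in both directions. Of 25 tested JAK-STAT components, 1 rose, 2 fell and 22 did not pass. Socs3, a feedback inhibitor of cytokine receptors, rose from 33.9 ± 2.31 to 65.0 ± 3.79 FPKM. Stat2, a transcription factor gene of interferon signalling, fell from 20.9 ± 1.13 to 13.7 ± 0.949 FPKM. Adjusted over the list alone 3 rose and 2 fell (camera adjusted p = 0.091, but 0.0424 without IL-17 library 3 and 0.0458 without control library 3). Among 15 tested JAK1-using receptors and STAT6-axis genes, Il4ra rose from 12.4 ± 0.794 to 16.9 ± 0.310 FPKM and Il13ra1 from 7.09 ± 0.781 to 10.7 ± 0.365 FPKM. They encode the chains of the IL-4 and IL-13 receptor. The other 13 did not pass, and adjusted over the list alone 4 rose and 1 fell (camera adjusted p = 0.12). Of 14 tested STAT6 target genes, Il4ra rose, Vcam1 fell and 12 did not pass, with 3 higher and 2 lower when adjusted over the list alone. That list's median was -0.04, its mean 0.02 and its camera direction down (adjusted p = 0.728). Chil3, an uncalled member named after its values were seen, was also among the lung transcripts described below. It was at 2.14, 1.25 and 3.05 FPKM with IL-17 and 0.334, 0.421 and 1.06 in controls. Its difference cannot be told apart from uneven lung transcripts. The limma adjusted p of Il4ra, with Benjamini-Hochberg adjustment, was 0.0147, and became 0.0828, 0.0589 and 0.0643 without IL-17 library 2, IL-17 library 3 and control library 2. That of Il13ra1 was 0.019, and became 0.095, 0.0541 and 0.0654 without IL-17 library 2, IL-17 library 3 and control library 3. Without both IL-17 library 1 and control library 3, 0 of the 15 passed.

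**Figure D2:**
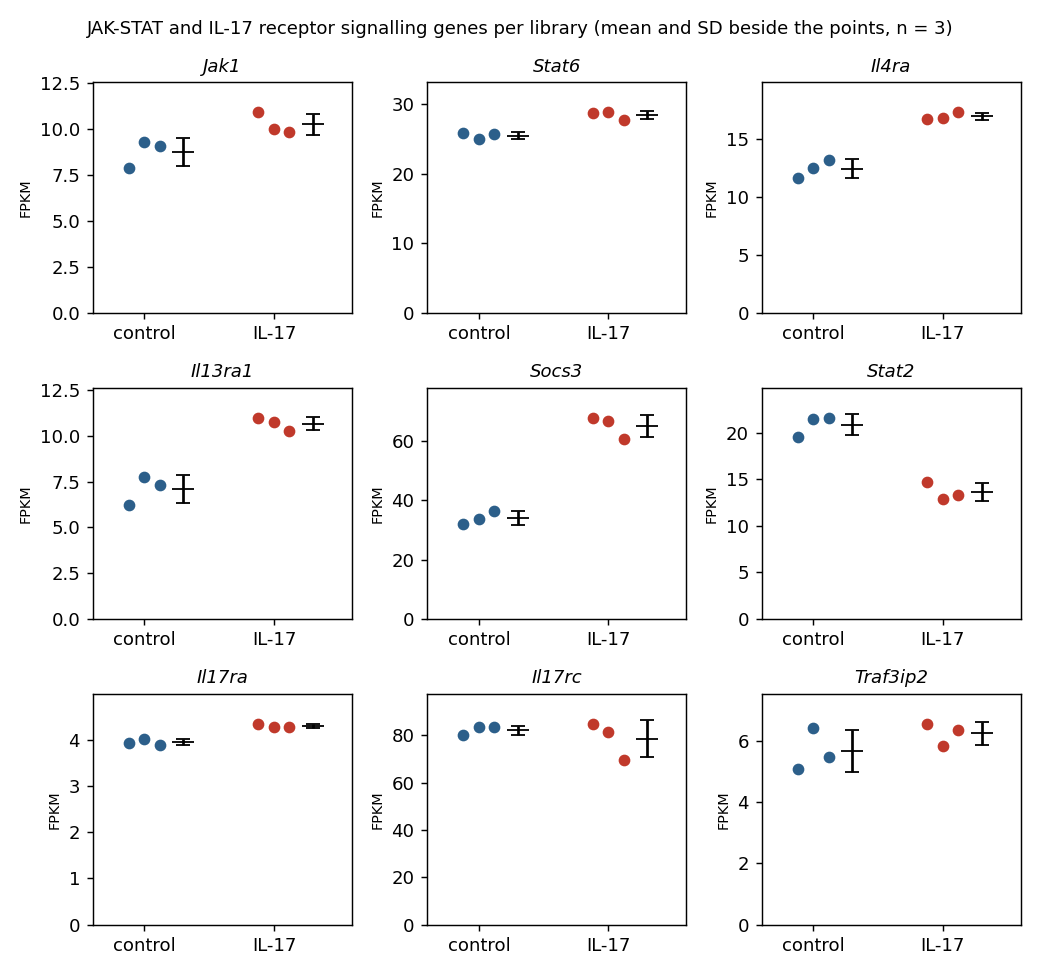
FPKM of 9 genes of JAK-STAT and IL-17 receptor signalling in each library (points; blue control, red IL-17), with the mean and SD of the 3 libraries beside them. Jak1 was at 8.74 in controls and 10.2 with IL-17, Stat6 at 25.5 and 28.5, Il4ra at 12.4 and 16.9, Socs3 at 33.9 and 65.0, and Stat2 at 20.9 and 13.7 FPKM.

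Genes known to respond to IL-17 were higher as a set. Of 30 tested IL-17 target genes, 12 rose, 2 fell and 16 did not pass; adjusted over the list alone, 16 rose and 3 fell. Those that rose included Il6, Lcn2 and Csf3. Those that fell were Cxcl10 and Tnf, a cytokine gene at 14.04 ± 0.757 FPKM in controls and 10.2 ± 0.730 FPKM with IL-17, named here after its values were seen. The median log2 fold change was 0.38 and the list was higher than other genes by camera (adjusted p = 1.27e-10), with adjusted p = 0.0377 with an estimated correlation. Some lung transcripts were also higher with IL-17, such as Sftpc, at 29.8, 25.8 and 35.3 FPKM against 0.331, 0.170 and 15.2 in controls. Without both IL-17 library 1 and control library 3, 9 of the 30 rose and 1 fell, with a median of 0.37. Of 33 tested genes of IL-17 receptor signalling, 0 passed limma over all genes and 0 adjusted over the list alone; camera gave adjusted p = 0.664 and fry 0.575. Il17ra stood at 4.29 ± 0.0365 FPKM with IL-17 and 3.94 ± 0.0679 in controls, Il17rc at 78.6 ± 7.83 and 82.3 ± 1.90, and the adaptor gene Traf3ip2 at 6.25 ± 0.366 and 5.66 ± 0.685. Their limma adjusted p-values, with Benjamini-Hochberg adjustment, were 0.391, 0.684 and 0.487. Among 28 NF-kB target genes, 3 rose and 4 fell. Ier3, an early response gene, rose by 0.52 (SE 0.05) and Bcl3, an NF-kB cofactor, by 0.72 (SE 0.10), while Cxcl10 and Vcam1 fell. Adjusted over the list alone 7 rose and 9 fell. Camera gave adjusted p = 0.244, while fry, which does not compare with other genes, gave adjusted p = 0.0333 downward. The Bcl3 call was lost without control library 1 (limma adjusted p = 0.0593) or control library 2 (0.0563).

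**Figure D3:**
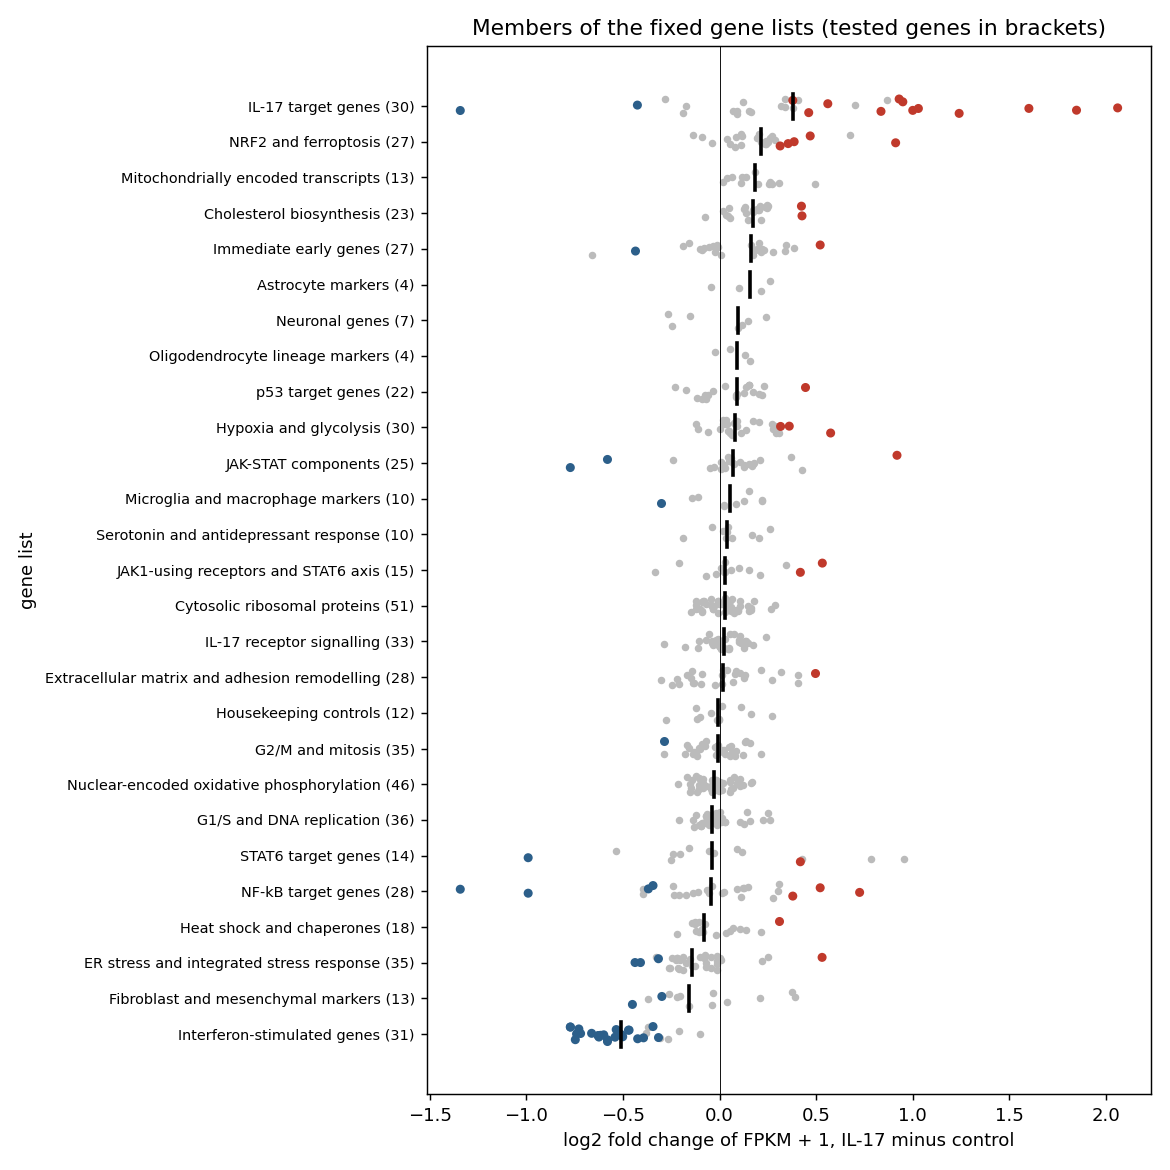
Log2 fold changes of FPKM + 1 (IL-17 minus control) for the tested members of each of 27 gene lists, with the number tested in brackets and a black bar at the list median. Red and blue points are members called higher and lower. The interferon-stimulated genes all lie below 0, with a median of -0.51, and the IL-17 target genes have a median of 0.38.

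Some antioxidant and sterol synthesis genes rose. Of 27 NRF2 and ferroptosis genes, 5 rose, 0 fell and 22 did not pass; adjusted over the list alone, 15 rose and 1 fell. Hmox1, the haem-degrading enzyme, rose from 262.7 ± 4.97 to 495.3 ± 29.5 FPKM. Tfrc, the transferrin receptor, Srxn1, sulfiredoxin, and Txnrd1, thioredoxin reductase, rose by 0.47, 0.39 and 0.35 on the log2 scale. The list was higher by camera (adjusted p = 1.3e-09), with adjusted p = 0.0798 with an estimated correlation. Its 5 calls became 1 without IL-17 library 2, 2 without IL-17 library 3, and 3, 2 and 3 without control libraries 1, 2 and 3, and 1 without both IL-17 library 1 and control library 3 (median 0.25, against 0.21 with all libraries). Among 23 cholesterol biosynthesis genes, Tm7sf2 and Idi1 rose, by 0.43 (SE 0.06) and 0.42 (SE 0.07), and 11 rose when adjusted over the list alone. Camera placed that list higher (adjusted p = 1.02e-07; adjusted p = 0.132 with an estimated correlation). Tm7sf2 was not called without IL-17 library 2, control library 2 or control library 3 (limma adjusted p = 0.0965, 0.0823 and 0.071). Idi1 was not called without IL-17 library 2 or 3 (0.0907 and 0.0568) or without control library 1, 2 or 3 (0.0715, 0.0964 and 0.109). Without both IL-17 library 1 and control library 3, 0 of the cholesterol genes passed (median 0.20, against 0.17).

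Of 35 genes of the endoplasmic reticulum and integrated stress responses, Ddit4, an mTORC1 inhibitor, rose by 0.53 (SE 0.05). Trib3, a pseudokinase, the amino acid transporter gene Slc7a5 and Asns, asparagine synthetase, fell by 0.44, 0.41 and 0.32 on the log2 scale. The other 31 did not pass, and adjusted over the list alone 3 rose and 16 fell. The list was lower by camera (adjusted p = 1.01e-07), with adjusted p = 0.0798 with an estimated correlation. Without IL-17 library 2 the limma adjusted p-values of Trib3, Slc7a5 and Asns became 0.0532, 0.171 and 0.177. Slc7a5 was also lost without IL-17 library 3 (0.113) and control libraries 1, 2 and 3 (0.0589, 0.156 and 0.166). Asns was also lost without IL-17 libraries 1 and 3 (0.088 and 0.086) and control libraries 1, 2 and 3 (0.121, 0.0557 and 0.168). Without both IL-17 library 1 and control library 3, 1 of the 35 rose and 0 fell (median -0.13, against -0.14). Of 30 hypoxia and glycolysis entries, 3 rose and 27 did not pass, with 6 higher when adjusted over the list alone. The 3 calls became 1 without IL-17 library 1, 2 or 3 and 0 without control library 1 or 2, and 1 without both IL-17 library 1 and control library 3. Bnip3, a mitophagy gene, went from 18.0 ± 1.40 to 27.3 ± 2.27 FPKM, and was not called without control library 1 or 2 (limma adjusted p = 0.0601 and 0.0523). That list was higher by camera (adjusted p = 0.000254), with adjusted p = 0.263 with an estimated correlation.

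Transcripts of the mitochondrial genome took 5.93%, 6.14% and 6.15% of FPKM in IL-17 libraries and 5.67%, 5.72% and 5.11% in controls. None of the 13 mitochondrially encoded transcripts passed limma over all genes; the count was 4 higher when adjusted over the list alone. Camera placed the list higher (adjusted p = 0.000676; adjusted p = 0.45 with an estimated correlation). Of 46 nuclear-encoded oxidative phosphorylation genes 0 passed limma; the median was -0.03 and turned to 0.01 under quantile normalization. Camera gave adjusted p = 0.0347 downward, and adjusted p = 0.617 with an estimated correlation. That call was lost without IL-17 library 1 (camera adjusted p = 0.436) or control library 1 (0.879), where the median turned to 0.006 and 0.02.

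The libraries carried few neuronal transcripts, many of mesenchymal type and some of those typical of macrophages. Of 34 neuronal genes, 24 were in the table and 5 had a mean of at least 1 FPKM. Tubb3, a neuronal tubulin, stood at 11.6 ± 0.416 FPKM with IL-17 and 13.97 ± 0.767 in controls, and Ncam1, an adhesion molecule, at 3.14 ± 0.316 and 3.98 ± 0.263; neither was called. Chosen after their values were seen, Map2 and Rbfox3, which mark mature neurons, averaged 0.242 ± 0.0441 and 0.0127 ± 0.0311 FPKM over the 6 libraries. Of 15 macrophage and microglia genes, 8 had a mean of at least 1 FPKM; Cd68 and Csf1r, also chosen after their values were seen, averaged 253.3 ± 16.4 and 20.5 ± 1.38 FPKM. Others of that list, chosen likewise, were near 0: Itgam averaged 0.160 ± 0.128, Aif1 0.264 ± 0.0893, Cx3cr1 0.0775 ± 0.0368 and P2ry12 0.0496 ± 0.0618 FPKM. Ptprc, the general leukocyte marker, averaged 0.899 ± 0.172 FPKM. Fibroblast and mesenchymal genes reached 1 FPKM in 13 of 15 cases, and S100a4, chosen likewise, averaged 2375 ± 148 FPKM. The identity of the cells was taken from the labels alone, so with these marker levels it remains in doubt which cell type the values describe.

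Between the groups, 2 of 13 tested fibroblast genes fell: Acta2, smooth muscle actin, from 133.4 ± 6.10 to 97.2 ± 0.734 FPKM and Vim, vimentin, from 274.3 ± 9.14 to 222.9 ± 7.72 FPKM. Adjusted over the list alone 1 rose and 2 fell, and camera gave adjusted p = 0.0347 downward, but adjusted p = 0.55 with an estimated correlation. The list was not called without IL-17 library 1 or 3 (camera adjusted p = 0.072 and 0.0968) or control library 2 or 3 (0.15 and 0.075), and without both IL-17 library 1 and control library 3 no member of it was called by limma. The Vim call was lost without any 1 of the 6 libraries (limma adjusted p = 0.0629, 0.122 and 0.109 without IL-17 libraries 1, 2 and 3, and 0.0601, 0.127 and 0.144 without control libraries 1, 2 and 3). Of 7 tested neuronal genes 0 passed limma over all genes; adjusted over the list alone 1 rose and 2 fell. The neuronal list's median was 0.10 and its mean -0.01, with camera downward (adjusted p = 0.728). Of 10 macrophage and microglia genes, Tmem119 fell by 0.30 (limma adjusted p = 0.0416) and 9 did not pass (camera adjusted p = 0.809). Its call was lost without IL-17 libraries 1, 2 and 3 (0.0629, 0.191 and 0.121) and control libraries 1, 2 and 3 (0.0822, 0.102 and 0.143). The astrocyte and oligodendrocyte lists had 4 tested genes each, too few for camera, and 0 called by limma.

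Genes of serotonin handling and antidepressant response were mostly not testable. Of 38 listed, 9 were not in the table, which holds no gene at 0 in every library, 19 lay below the filter and 10 were tested, of which 0 passed limma over all genes or over the list alone (camera adjusted p = 0.555). Bdnf, a neurotrophin gene, stood at 0.744 ± 0.107 FPKM with IL-17 and 0.989 ± 0.0843 in controls, and Arc, an activity-regulated gene, at 1.01 ± 0.104 and 0.749 ± 0.187 FPKM. Of 36 G1/S genes 0 passed, and of 35 G2/M genes Ube2c alone did, lower by 0.28 on the log2 scale (camera adjusted p = 0.124 and 0.126). Among 22 p53 targets Gadd45a alone rose, among 18 chaperones Hsp90aa1 alone and among 28 matrix genes Timp1 alone, by 0.44, 0.31 and 0.50 on the log2 scale (camera adjusted p = 0.198, 0.257 and 0.958). Of 27 immediate early genes Ier3 rose and Ccn1 fell, by 0.43; adjusted over the list alone 8 rose and 2 fell (camera adjusted p = 0.126). Timp1 and Ier3 stayed called with any 1 library left out, whereas Ube2c and Hsp90aa1 were lost in each such fit (highest limma adjusted p = 0.176 and 0.167, both without IL-17 library 2). Gadd45a was lost without IL-17 libraries 1, 2 and 3 (0.0612, 0.126 and 0.0848) and control library 2 (0.0977), and Ccn1 without IL-17 library 2 (0.058) and control libraries 2 and 3 (0.0547 and 0.0658). Of 51 cytosolic ribosomal protein genes and 12 housekeeping genes, 0 passed limma (camera adjusted p = 0.763 and 0.387), where 2167 of all tested genes had an unadjusted p under 0.05. The ribosomal median was 0.03 with camera downward, and it was -0.01 under TMM scaling. Without control library 1 the ribosomal list passed camera upward (adjusted p = 0.0289). Of the 25 lists tested, 9 passed camera, of which 2 passed with an estimated correlation and 6 by fry. Fry passed 1 further list, the NF-kB targets. When the libraries were regrouped so that each group mixed both treatments, camera with the preset correlation still called 1 to 8 lists. Such a call, however small its adjusted p, therefore does not by itself tie a list to IL-17.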

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

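All alternatives named as added were chosen after seeing the data. The 252 calls kept their direction in every alternative that tested them. Their groups did not overlap, so a direction could have turned only under another scaling or the GC and length correction. The genes called did differ: without IL-17 library 1, 172 of the 251 calls were shared with the main comparison. The count was 135 with no filter (63 higher, 72 lower; more genes tested), 1015 with array weights (497 and 518), 20 at a log2 change of at least 1 (18 and 2), and 106 at an adjusted p under 0.01 (47 and 59). Under TMM scaling 203 were lower. The added GC and length correction gave 457 (253 and 204), protein-coding genes alone gave 189 higher, and leaving out IL-17 library 1 and control library 3 gave 160 (68 higher; fewer samples). Leaving out 1 library gave 117 to 251 calls, 57 to 109 higher and 60 to 142 lower, and 7 to 9 lists. With the replicate number as a block, 80 genes were called (41 and 39). Deviations of equally numbered libraries correlated at -0.144, 0.0801 and 0.206, so the pairing is not shown by the data. An estimated correlation left 2 of 9 lists. Stat6 passed with array weights (log2 fold change 0.16, limma adjusted p = 0.0396); Jak1 passed in 0 of 21 alternatives (0.118 to 0.464). With 1 library left out, Il17rc ran from -0.13 to 0.0126 (without IL-17 library 3) and CT010467.1 from -0.0986 (without IL-17 library 2) to 0.244. In such fits the ribosomal protein median ran from -0.0274 to 0.0831 (without control library 1, where the list passed camera upward, adjusted p = 0.0289). Where no reason is given, the cause was not tested. Of 49 called named genes, 22 passed in every alternative. The tests foreseen for raw counts were not run, because the table holds none. Without counts, no counting error could be given for low genes.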

Other observations

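The family tests and the choice of genes here, the test of control library 3 for interferon-stimulated genes, the test of induction by IL-17 for lung transcripts and the check of gene models against the order of liver transcripts were chosen only after the results were seen. Genes were grouped by the root of their symbol into 353 families of at least 5 tested genes. By Fisher's exact test with Benjamini-Hochberg adjustment over 706 tests, 5 of 6 Oas genes, sensors of double-stranded RNA, fell (adjusted p = 3.8e-07), as did 5 of 12 Parp genes (2.4e-05) and 5 of 27 genes of the H2 histocompatibility complex (0.000737). Interleukin and interleukin receptor genes were over-represented among those that rose, with 6 of 27 (3.8e-05), including Il33, an alarmin, from 4.18 ± 0.234 to 11.1 ± 0.232 FPKM (n = 3). The Serpina family, protease inhibitors of the acute phase, had 4 of 12 higher (0.000638). Members of a family can share reads and regulation, so these p-values treat related genes as independent. Mitochondrial transfer RNA genes fell in 4 of 37 tested genes of the mitochondrial genome (0.0377). Of these, mt-Tw went from 49.5 ± 3.75 to 32.2 ± 0.400 FPKM, while all 13 protein-coding transcripts of that genome had positive log2 fold changes. Polyadenylated RNA was captured and strand use was not stated, so it is uncertain what the values of such short genes measure.

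Among other called genes, Ptgs2, the inducible cyclooxygenase, rose from 7.65 ± 0.905 to 19.4 ± 0.644 FPKM, and the chemokine gene Cx3cl1 from 67.1 ± 4.71 to 148.5 ± 13.8 FPKM. Saa3, an acute-phase apolipoprotein, rose from 899 ± 66.1 to 1799 ± 129 FPKM. The metallothionein genes Mt1 and Mt2 rose by 0.60 and 0.76 on the log2 scale. Zc3h12a, an RNase that degrades inflammatory transcripts, rose from 32.8 ± 1.65 to 63.3 ± 3.27 FPKM, and Nfkbiz, an NF-kB cofactor, from 9.73 ± 0.297 to 18.1 ± 0.191 FPKM. Ccnd1, cyclin D1, fell from 37.3 ± 1.67 to 27.1 ± 0.701 FPKM. Of these genes, Ptgs2, Saa3, Zc3h12a and Nfkbiz belong to the fixed list of IL-17 target genes and were already counted there.

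The 5 transcripts of highest mean level were CT010467.1, Ftl1, Lgals1, Gm10925 and mt-Atp8. CT010467.1 is annotated as ribosomal RNA and Gm10925 as an unprocessed pseudogene. CT010467.1 stood at 7902 ± 2242 FPKM with IL-17 and 7099 ± 713 in controls, and was not called. It was uneven between libraries, at 10488 FPKM in IL-17 library 2 and 6520 to 7907 in the others. The split by treatment called 252 genes, 123 higher and 129 lower, against at most 1 in each of the 9 other ways of dividing the 6 libraries into 3 and 3. For gene lists by camera the real split gave 9 and the other splits 1 to 8, so camera also called lists when treatments were mixed. In each case the real split alone reached its own count, but with 10 splits a share under 0.05 cannot be reached.

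The fall of interferon-stimulated genes, with a median log2 fold change of -0.51, was set against 3 technical explanations. Library scaling is argued against by the median nearest 0 over TMM, quantile and TPM scaling, -0.50. GC content or transcript length is argued against by a median of -0.52 after correction for both. Dilution by lung RNA that lowered all genes alike is argued against by the median log2 fold changes of other genes. These were 0.016 over all tested genes and -0.008 over the housekeeping genes. Any other contribution of lung RNA in the IL-17 libraries stays open. Control library 3, which also carried lung RNA, differed from the other controls by a median of 0.00964 over the list (quartiles -0.03 and 0.06), but that is 1 library. An effect of IL-17 and a difference in culture state between the groups, both untested, stay open too.

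Lung and liver transcripts were present at uneven levels. Sftpc, a surfactant gene of the lung, was at 29.8, 25.8 and 35.3 FPKM in IL-17 libraries 1 to 3 and at 0.331, 0.170 and 15.2 in control libraries 1 to 3; Alb, albumin of the liver, was at 51.4, 6.75 and 10.8 and at 47.1, 40.4 and 27.5. In control library 3, which had no IL-17, lung transcripts exceeded those of the other controls by a median log2 ratio of 3.16 over 12 genes; these were picked for their uneven levels and this is 1 library, so induction by IL-17 stays open. On lists fixed before their values were seen, 11 of 20 detected lung transcripts followed the same order of libraries (binomial p = 1.1e-08) and 28 of 28 liver transcripts theirs (p = 1.2e-33), where chance gives 6.67% and other tested genes gave 11.3% and 11.4%. Transcripts of the same tissue can vary together, and the binomial test treats them as independent and uses 6.67% as its expectation. Its p-values may therefore overstate the evidence. RNA or reads from lung and liver material is a candidate explanation, and the step at which it may have entered was not tested.

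Some gene models were near 0 in certain libraries and high in others. Gm45717 was at 445.6 to 540.5 FPKM in 5 libraries and 0.238 in control library 3, and Gm26619 at 0, 0 and 648.1 in IL-17 libraries and 364.0, 0 and 540.0 in controls. Of 13 such models, 5 overlapped an exon of another gene on the same strand, 38.5% against 8.84% of 9306 other genes at this level (odds ratio 6.44, Fisher's exact p = 0.00384). Assignment of shared reads to one model or the other may account for the overlapping ones. Of the other 8, the liver genes Mup7, Mup20 and Serpina1e had the order of libraries of the liver transcripts, and for the remaining 5 no explanation was tested.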
